A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

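Total RNA from yeast sampled at 6 time points of 2 stress courses was hybridised to 12 one-colour Affymetrix Yeast Genome arrays as biotin-labelled cRNA made from poly(T)-primed cDNA, per the labels. The deposited values are log2 probe set signals made by RMA, per the submitters' processing notes, which state neither the version nor whether all arrays were normalized together. The array medians of the deposited values lay between 9.01 and 9.15 log2, and no further scaling was applied. The table held 5900 probe sets, of which 184 were controls. Of the other 5716, 5498 were listed with 1 gene and 218 with none. For 47 genes with several probe sets the brightest was used, which gave 5449 genes. Symbols were updated for 12 genes.

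A model with 5 groups (time 0, and the early and late windows of each stress) was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 7 residual degrees of freedom and 2.71 prior degrees of freedom. The 9 contrasts set each window against time 0, late against early windows, MMS against H2O2 in each window, and the late minus early change of MMS against that of H2O2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 5449 genes. Changes are log2 differences with the model's SE. Counts of genes 2-fold or more away from the 0 min array of the same course come from 1 array per time point and carry no test. The fit was tested on simulated data in which 200 genes were changed. A log2 change of 1 was recovered for 73.1% of genes in the early H2O2 contrast and 86.6% in the late MMS contrast, and a log2 change of 0.5 for 20.9% and 34.3%. False calls were 5 of 129 and 8 of 151 calls in these contrasts. They were 9 of 142 for MMS against H2O2 early, 12 of 154 for MMS late against early and 18 of 173 for MMS against H2O2 late. Of these shares, all but the 5 of 129 lay above the 0.05 aimed at. The simulated noise was independent between arrays, whereas the measured spread also holds change within a window. Far fewer genes were changed in the simulation than were called in the data, so the recovery there can differ.

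Gene lists were fixed before the data were examined and number 29. They hold Yap1/Skn7 antioxidant genes, NADPH supply, Msn2/4 general stress genes, the Mec1/Dun1 ribonucleotide reductase regulon, DNA repair, the DNA damage checkpoint, proteasome subunits, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, Hsf1 chaperones, the unfolded protein response, Gcn4 amino acid synthesis, sulfur and methionine, G1/S and DNA replication, histones, the CLB2 cluster of G2/M, M/G1 and daughter-cell genes, respiration and the TCA cycle, mitochondrial ribosomal proteins, glycolysis and fermentation, ergosterol synthesis, iron uptake, pleiotropic drug resistance, mRNA decay, autophagy, cell wall integrity, and, for other cell states, sporulation and mating. Each was tested against the other genes with camera (two-sided, preset correlation 0.01), adjusted over the lists of a contrast. The test was repeated with the correlation estimated per list (statmod 1.5.0). The lists were also tested with fry, which sets a list against no change and not against the other genes. Of 261 list tests 139 passed with the preset correlation and 0 with the estimated one, where the lowest adjusted p was 0.178. The estimate came from residuals with 7 degrees of freedom, which also hold change within a window that genes of a list can share. A list that failed with it is therefore not shown to be unchanged. Members were also counted with p-values adjusted over the list alone. The ribosomal protein list was taken by name pattern and includes RPP1, an RNase P subunit. The cell wall list holds MLP1, which now names a nuclear pore protein and not the kinase that was meant. Of the 128 ribosomal protein probe sets 25 are of a type shared between similar genes, as are those of 5 of the 398 named genes (HTA2, RPL41A, TPO2, DDI3 and HHF1).

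The rule for named genes took, for each window against time 0, the 6 largest rises and 6 largest falls among called genes whose window arrays all lay outside both arrays at 0 min. It also took up to 4 members of each list with the largest change in each contrast, the 6 largest differences in each direction of the late against early and MMS against H2O2 contrasts, and a fixed set (YAP1, TRX2, TRR1, TSA1, SRX1, GPX2, CTT1, HSP12, RPN4, RNR1 to RNR4, HUG1, RAD54, MAG1, PHR1 and ACT1). Genes named without a value, beside counts of 5 or fewer or as the exceptions of a list, were chosen after their values were seen where the rule did not take them. The alternatives were the 0 min array of the same course as baseline, arrays centred on their medians, quantile normalization, the dimmest 25% of genes left out, a mean-variance trend with robust moderation, the mean of all probe sets, all probe sets except controls, early windows of 30 min only or 30 to 100 min (the late windows then held 60 to 180 min or 140 and 180 min), time point as a block, fold thresholds of 1.5 and 3, and leaving out each array in turn. RNA quality was read from 3′ and 5′ probe sets of 8 yeast control genes and 4 added poly-A transcripts. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.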

Results

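Messenger RNA levels of the budding yeast Saccharomyces cerevisiae were followed for 180 min after cells growing in rich medium at 25 °C received 0.3 mM hydrogen peroxide, an oxidant, or 0.1% methyl methanesulfonate (MMS), which alkylates DNA bases. Each of the 2 courses held arrays at 0, 30, 60, 100, 140 and 180 min, with 1 array per stress and time point and 12 arrays in all. The 2 arrays at 0 min formed the time 0 group. The arrays at 30 and 60 min formed the early window of a stress (n = 2) and those at 100, 140 and 180 min its late window (n = 3). The time points of a course stood in for replicates, so that the adjusted p-values compare windows against the spread among these time points and not among repeat cultures. Values were log2 signals of 5449 genes, with array medians over these genes between 9.06 and 9.20 and a median residual SD of 0.169. The small number of arrays limits the precision of every value. Changes are given as log2 change ± SE from the limma fit, with the fold where it is large. Counts within a gene list are over all genes tested, and those adjusted over the list alone follow where they differ.

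The arrays at 0 min of the 2 courses were close to each other, with a Pearson correlation across genes of 0.998 (genes are not independent replicates) and an SD of the log2 difference of 0.150. Of the 5449 genes, 6 were 2-fold or more higher and 1 was 2-fold or more lower in the MMS course at 0 min. After peroxide the number of changed genes peaked at 60 min and then shrank. The number of genes 2-fold or more away from the 0 min array of the same course was 631 at 30 min, 957 at 60 min, 564 at 100 min, 351 at 140 min and 221 at 180 min, and 22 of those at 180 min were lower. After MMS the number kept growing, with 310, 1169, 1735, 1933 and 2047 genes at the same time points, of which 969 were lower at 180 min. The SD of the log2 change across genes grew less, at 1.25, 1.32 and 1.33 at 100, 140 and 180 min of MMS. The correlation across genes with the 0 min array of the same course was lowest at 60 min after peroxide (0.908) and had returned to 0.976 at 180 min, whereas after MMS it was 0.895 at 60 min and 0.805 at 180 min. These counts come from 1 array each and carry no test.

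**Figure D1:**
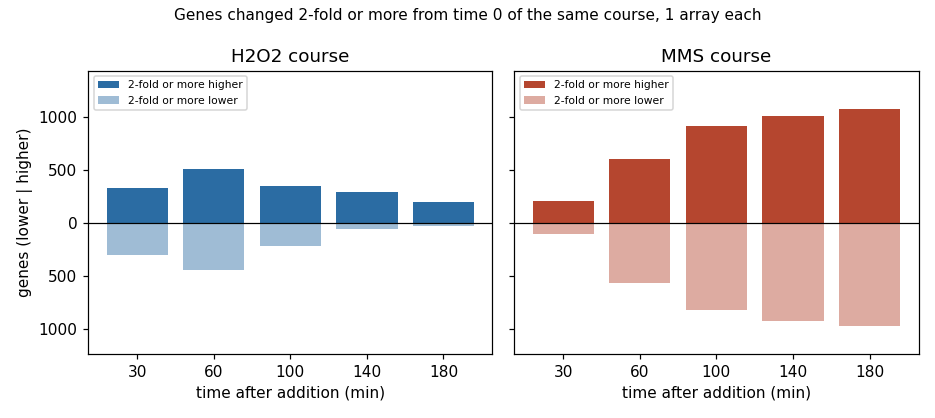
Number of genes 2-fold or more higher (dark bars, above 0) or lower (light bars, below 0) than on the 0 min array of the same course, against time in min, for the H2O2 course (left) and the MMS course (right), 1 array per bar. The H2O2 bars are tallest at 60 min (514 higher, 443 lower) and shrink to 199 and 22 at 180 min, whereas the MMS bars reach 1078 and 969 at 180 min.

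The comparison of the early H2O2 window with time 0 asked which transcripts responded within the hour after oxidant was added. Transcripts for peroxide removal and general stress protection rose strongly, and transcripts for ribosome assembly and cell-cycle entry fell. The 6 largest rises were YDL218W, an uncharacterised gene (166-fold, log2 7.37 ± 1.01, adjusted p = 0.00179), TSA2 (YDR453C), a stress-induced thioredoxin peroxidase (139-fold, log2 7.12 ± 0.57, adjusted p = 0.000316), FRM2, a nitroreductase-like protein (136-fold, log2 7.09 ± 1.01), SRX1 (YKL086W), the sulfiredoxin that restores over-oxidised peroxiredoxins (96.7-fold, log2 6.60 ± 0.73, adjusted p = 0.000746), DDR2, a multi-stress gene (68.6-fold, log2 6.10 ± 0.51), and OYE3, an NADPH oxidoreductase (59.8-fold, log2 5.90 ± 1.01). The 6 largest falls were DHR2, an RNA helicase of ribosome assembly (-3.16 ± 0.54), AAH1, adenine deaminase (-2.89 ± 0.95), JJJ3 (-2.80 ± 0.60), TOD6, a repressor of ribosome biogenesis genes (-2.44 ± 0.45), DBP7, a further helicase of ribosome assembly (-2.39 ± 0.37), and YGR035C (-2.34 ± 0.71). For each of these genes every array of the window lay outside both arrays at 0 min. ACT1, actin, was measured at 0.02 ± 0.09, adjusted p = 0.878.

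Among the Yap1/Skn7 antioxidant genes, 23 of 31 rose and 1, SKN7, fell (median log2 1.16, camera adjusted p = 5.75e-12, adjusted p = 0.479 with an estimated correlation, 26 up and 1 down adjusted over the list alone). CTA1 and CTT1, the peroxisomal and cytosolic catalases, rose by 5.72 ± 0.54 and 4.56 ± 0.64. TRX2, TRR1 and YAP1 rose by 0.64 ± 0.15, 1.14 ± 0.33 and 1.16 ± 0.22. TSA1 (0.32 ± 0.14, adjusted p = 0.0962) and GPX2 (2.61 ± 0.97, adjusted p = 0.064) did not pass the test. Of the NADPH supply genes, 6 of 15 rose (median log2 0.38, camera adjusted p = 0.0168, adjusted p = 0.479 with an estimated correlation, 7 up and 0 down adjusted over the list alone), among them SOL4 (4.37 ± 0.69) and NQM1 (2.44 ± 0.40) of the pentose phosphate pathway and ZWF1 (1.97 ± 0.30), its entry enzyme. The Msn2/4 general stress genes rose in 30 of 36 cases and none fell (median log2 1.95, camera adjusted p = 2.97e-15, adjusted p = 0.479 with an estimated correlation). TSL1, a trehalose synthase subunit, was at 4.06 ± 0.43, GAD1 at 3.37 ± 0.61 and PGM2 at 3.37 ± 0.73. HSP12 was at 1.95 ± 0.85, adjusted p = 0.104. Autophagy genes rose in 13 of 21 cases (median log2 0.90, camera adjusted p = 5.08e-06, adjusted p = 0.52 with an estimated correlation, 15 up and 0 down adjusted over the list alone), including the vacuolar aminopeptidase APE1 (4.18 ± 0.43) and the kinase ATG1 (2.28 ± 0.35). Of the sulfur and methionine genes, 8 of 25 rose (median log2 0.66, camera adjusted p = 0.000421, adjusted p = 0.52 with an estimated correlation). MET28 was at 3.13 ± 0.45. Of the iron uptake genes, 8 rose and 1 fell (median log2 0.14, camera adjusted p = 0.00841, adjusted p = 0.479 with an estimated correlation). The iron-sulfur scaffold ISU2 (2.05 ± 0.19) and the mitochondrial iron carrier MRS4 (1.74 ± 0.18) rose, and the ferric reductase FRE4 (-2.03 ± 0.47) fell. Respiration and TCA cycle genes rose in 12 of 47 cases (median log2 0.13, camera adjusted p = 0.00205, adjusted p = 0.52 with an estimated correlation, 11 up and 0 down adjusted over the list alone). CYC7, the stress isoform of cytochrome c, was at 3.19 ± 0.42.

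Smaller shifts upward were measured for mitochondrial ribosomal proteins, with 7 of 54 members passing (median log2 0.31, camera adjusted p = 1.85e-06, adjusted p = 0.609 with an estimated correlation, 0 up and 0 down adjusted over the list alone). Hsf1 chaperones followed, with 3 of 18 passing, HSP82 (1.69 ± 0.32), BTN2 (1.06 ± 0.35) and MDJ1 (median log2 0.21, camera adjusted p = 0.0348, adjusted p = 0.623 with an estimated correlation, 1 up and 0 down adjusted over the list alone). The proteasome subunit list stood above other genes (median log2 0.28, camera adjusted p = 0.000344, adjusted p = 0.628 with an estimated correlation), with 0 of 33 members called by limma and 4 at an unadjusted p under 0.05. RPN4, the proteasome gene activator, rose by 0.59 ± 0.18. Ribosome biogenesis genes fell in 72 of 89 cases (median log2 -1.65, camera adjusted p = 3.91e-17, adjusted p = 0.52 with an estimated correlation, 0 up and 83 down adjusted over the list alone). MAK16 was at -2.31 ± 0.50 and ENP2 at -2.30 ± 0.43. Subunits of RNA polymerases I and III fell in 18 of 21 cases (median log2 -1.37, camera adjusted p = 1.6e-06, adjusted p = 0.52 with an estimated correlation, 0 up and 21 down adjusted over the list alone). RPC82 was at -1.84 ± 0.33. Of the cytosolic ribosomal protein list 2 of 128 fell, RPL41A and RPP1, the latter an RNase P subunit that the list's name pattern takes in, and the list did not pass (median log2 -0.06, camera adjusted p = 0.323, 0 up and 1 down adjusted over the list alone). Among cell-cycle genes, G1/S and DNA replication fell in 20 of 33 cases (median log2 -0.59, camera adjusted p = 1.52e-05, adjusted p = 0.479 with an estimated correlation, 1 up and 24 down adjusted over the list alone). The cyclin genes PCL1 (-1.82 ± 0.40), CLB6 (-1.51 ± 0.39) and CLN2 (-1.22 ± 0.34) were among them. The CLB2 cluster fell in 8 of 18 (median log2 -0.86, camera adjusted p = 0.000111, adjusted p = 0.526 with an estimated correlation, 0 up and 14 down adjusted over the list alone). CLB1 was at -1.41 ± 0.40 and CLB2 at -1.39 ± 0.35. The M/G1 list fell with 4 of 20 members passing, the replication licensing genes MCM3, MCM5 and MCM7 and the fatty acid gene FAA3 (median log2 -0.59, camera adjusted p = 0.0242, adjusted p = 0.623 with an estimated correlation, 0 up and 2 down adjusted over the list alone). The mRNA decay machinery fell in 19 of 46 cases and rose in 1, EDC2 (median log2 -0.22, camera adjusted p = 0.00133, adjusted p = 0.479 with an estimated correlation). The DNA damage checkpoint list fell with 4 of 13 members passing, PDS1, RAD9, LCD1 and MEC3 (median log2 -0.30, camera adjusted p = 0.0457, adjusted p = 0.526 with an estimated correlation).

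DNA repair genes went both ways, 7 up and 6 down of 41 (median log2 0.08, camera adjusted p = 0.469, 7 up and 7 down adjusted over the list alone). MAG1 (YER142C), the alkyladenine glycosylase, rose by 2.13 ± 0.42, adjusted p = 0.00624, the photolyase gene PHR1 by 1.73 ± 0.26, adjusted p = 0.00259 and NTG1, an oxidative base-damage glycosylase, by 1.33 ± 0.22. OGG1, the oxoguanine glycosylase, fell by 1.38 ± 0.25. RAD54 was at 0.85 ± 0.31, adjusted p = 0.0571. In the ribonucleotide reductase regulon 3 of 11 genes rose and 1, TOS4, fell (median log2 0.21, camera adjusted p = 0.153). RNR3, the damage-induced large subunit, rose by 1.56 ± 0.43, PLM2 by 1.31 ± 0.25 and RFX1, the regulon's repressor, by 0.85 ± 0.13. HUG1 was at 0.89 ± 0.55, adjusted p = 0.229, RNR1 at -0.84 ± 0.36, adjusted p = 0.101, RNR2 at 0.21 ± 0.12 and RNR4 at 0.07 ± 0.13. Histones (2 of 9 down, HTA1 and HHT1, median log2 -0.43, camera adjusted p = 0.052) and ergosterol synthesis (1 of 24 down, median log2 -0.23, camera adjusted p = 0.0624, 0 up and 0 down adjusted over the list alone) did not pass as lists. Neither did pleiotropic drug resistance (5 of 22 up, median log2 0.19, camera adjusted p = 0.0725), glycolysis and fermentation (1 of 20 up, median log2 0.04, camera adjusted p = 0.452), cell wall integrity (1 of 20 up, PIR3, median log2 0.11, camera adjusted p = 0.507, 0 up and 0 down adjusted over the list alone) or the mating response (1 up and 5 down of 22, median log2 -0.29, camera adjusted p = 0.065). The unfolded protein response (1 up and 1 down of 14, median log2 -0.03, camera adjusted p = 0.963, 0 up and 1 down adjusted over the list alone), the Gcn4 amino acid genes (6 up and 2 down of 48, median log2 -0.06, camera adjusted p = 0.963, 4 up and 1 down adjusted over the list alone) and the sporulation genes (4 up and 3 down of 23, median log2 -0.02, camera adjusted p = 0.719) did not pass either. In these 3 lists the median was negative while the test pointed upward, with means of 0.01, 0.00 and 0.04. TDH1 of the glycolysis list rose by 2.18 ± 0.19 and ERG11 of the ergosterol list fell by 0.69 ± 0.24.

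In all, 799 genes rose and 1035 fell of 5449, and 376 and 337 of them changed 2-fold or more. With arrays centred on their medians 911 were higher and 884 lower, so that the excess of falls was not kept. The total of 1834 was 600 against the 0 min array of the H2O2 course alone, 261 when the early window held 30 min only, and 1122 when it held 30 to 100 min. Here and below, the late window took the remaining times whenever the early one was changed. It was 817 without the 60 min H2O2 array and 585 or 600 without the 0 min array of the H2O2 or the MMS course.

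The late H2O2 window was compared with the same time 0 arrays. From 100 to 180 min 839 genes were called against 1834 early. The general stress, respiration and ribonucleotide reductase lists stood above other genes with the preset correlation, though not with an estimated one. The 6 largest rises were TSA2 (125-fold, log2 6.96 ± 0.52, adjusted p = 0.000257), YDL218W (29.4-fold, log2 4.88 ± 0.92), DDR2 (24.5-fold, log2 4.62 ± 0.46), SOL4 (17.5-fold, log2 4.13 ± 0.63), HXK1, a hexokinase made when glucose is low (17.4-fold, log2 4.12 ± 0.62), and GPH1, glycogen phosphorylase (16.3-fold, log2 4.03 ± 0.71). The 6 largest falls were AQY2, an aquaporin (-2.91 ± 0.51), BSC1 (-2.64 ± 0.64), SFG1 (-2.54 ± 0.41), YLL053C (-2.42 ± 0.47), FRE4 (-2.14 ± 0.43) and SPS4 (-2.11 ± 0.21). HUG1 (YML058W-A), a Mec1 target in the nucleotide supply response, rose by 3.72 ± 0.50, adjusted p = 0.00538, against 0.89 ± 0.55 early, where it did not pass. SRX1 was at 1.10 ± 0.66, adjusted p = 0.266, YAP1 at -0.18 ± 0.20, adjusted p = 0.543 and CTT1 at 1.95 ± 0.59, adjusted p = 0.0507.

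In this window 32 of 36 Msn2/4 genes were above time 0 (median log2 1.62, camera adjusted p = 6.73e-21, adjusted p = 0.428 with an estimated correlation, 34 up and 0 down adjusted over the list alone). HSP12 was at 3.46 ± 0.78. Respiration and TCA cycle genes were up in 23 of 47 cases (median log2 0.41, camera adjusted p = 3.24e-16, adjusted p = 0.178 with an estimated correlation, 29 up and 0 down adjusted over the list alone), including CYC7 (3.17 ± 0.39), the NADH dehydrogenase NDE2 (1.66 ± 0.38), CIT1 (1.44 ± 0.21) and IDH1 (1.28 ± 0.19). The ribonucleotide reductase regulon rose in 6 of 11 cases (median log2 0.44, camera adjusted p = 0.000337, adjusted p = 0.543 with an estimated correlation, 7 up and 0 down adjusted over the list alone). RNR3 was at 2.61 ± 0.39, RNR2 at 0.63 ± 0.11 and RNR4 at 0.50 ± 0.12. NADPH supply (5 of 15 up, camera adjusted p = 0.000258, adjusted p = 0.178 with an estimated correlation) and autophagy (7 of 21 up, camera adjusted p = 4.51e-05, adjusted p = 0.67 with an estimated correlation) stood above other genes. So did glycolysis and fermentation (3 of 20 up, TDH1, ENO1 and HXT4, camera adjusted p = 0.00219, adjusted p = 0.67 with an estimated correlation) and the antioxidant genes (9 up and 2, SKN7 and CCS1, down of 31, camera adjusted p = 0.000149, adjusted p = 0.67 with an estimated correlation). Adjusted over the list alone, the counts higher were 8, 8, 3 and 11, with 2 antioxidant genes lower. Ribosome biogenesis remained below other genes as a list, with 1 of 89 members passing, RIO1 (median log2 -0.77, camera adjusted p = 8.47e-09, adjusted p = 0.702 with an estimated correlation, 0 up and 0 down adjusted over the list alone). The CLB2 cluster was likewise low (2 of 18 down, CLB2 and HST3, median log2 -0.59, camera adjusted p = 0.000239, adjusted p = 0.67 with an estimated correlation, 0 up and 7 down adjusted over the list alone) and the mRNA decay machinery (13 of 46 down and EDC2 up, median log2 -0.29, camera adjusted p = 5.43e-06, adjusted p = 0.272 with an estimated correlation, 2 up and 17 down adjusted over the list alone). The Gcn4 list did not pass (camera adjusted p = 0.99; median -0.09, mean 0.02, test downward). SNO1 and SNZ1, vitamin B6 synthesis genes, rose by 3.01 ± 0.36 and 1.87 ± 0.37.

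Tested directly, late against early, 235 genes were higher and 259 lower. SRX1 (-5.50 ± 0.66), CTA1 (-4.74 ± 0.49), AAD6, an aryl-alcohol dehydrogenase-like gene (-4.27 ± 0.41), HSP30 (-3.94 ± 0.63), OYE3 (-3.91 ± 0.92), ISU2 (-2.73 ± 0.18) and YAP1 (-1.35 ± 0.20) fell. HUG1 rose by 2.83 ± 0.50, FRE7 by 2.78 ± 0.55, the phosphate transporter PHO84 by 2.27 ± 0.44, FUR4 by 2.11 ± 0.39 and DHR2 by 1.97 ± 0.49. As lists, antioxidant genes fell between the windows (13 of 31 members, median log2 -0.90, camera adjusted p = 8.77e-08, adjusted p = 0.714 with an estimated correlation, 2 up and 19 down adjusted over the list alone). G1/S and DNA replication genes (10 of 33 members, median log2 0.45, camera adjusted p = 1.25e-07, adjusted p = 0.714 with an estimated correlation, 20 up and 0 down adjusted over the list alone) rose. The ribosome biogenesis list moved upward against other genes, with 4 of 89 members passing, DBP7, UTP6, BFR2 and NOP8 (median log2 0.84, camera adjusted p = 1.04e-11, adjusted p = 0.714 with an estimated correlation, 0 up and 0 down adjusted over the list alone). The Msn2/4 list was not called (median log2 -0.20, camera adjusted p = 0.124), with 0 of 36 members called by limma and 8 at an unadjusted p under 0.05.

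Against time 0 the late window had 497 genes higher and 342 lower, 231 and 22 of them by 2-fold or more. The total of 839 rested on both arrays at 0 min: it was 6 against the 0 min array of the H2O2 course, 9 without that array, 22 with windows of 30 to 100 min and of 140 and 180 min, 232 and 138 without the 100 and the 140 min H2O2 array, 516 without the 140 min MMS array, 6 without the 0 min array of the MMS course and 1271 without the 30 or the 60 min MMS array. The 6 genes, read after the values were seen, were GPM2, TSA2, YER053C-A, TDH1, DDR2 and SPS4. The late against early total of 494 was 266 with own 0 min arrays, 87 with an early window of 30 min only, 16 with one of 30 to 100 min and 302 without the dimmest 25% of genes. It was 85, 129 and 147 without the 30, 140 and 180 min H2O2 array, 266 without either array at 0 min, 269 without the 140 min MMS array and 965 without the 30 or the 60 min MMS array.

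The early MMS window asked which transcripts responded in the hour after the alkylating agent. Antioxidant, general stress and proteasome genes rose as lists, and ribosome biogenesis genes fell, all calls that were lost with an estimated correlation. The 6 largest rises were SRX1 (98.4-fold, log2 6.62 ± 0.73, adjusted p = 0.000877), DDI3 (YFL061W), a DNA-damage-inducible gene with a near-identical copy, DDI2, that the array does not separate (93.3-fold, log2 6.54 ± 0.35, adjusted p = 1.54e-05), FRM2 (56.6-fold, log2 5.82 ± 1.01), TSA2 (42.9-fold, log2 5.42 ± 0.57), OYE3 (42.2-fold, log2 5.40 ± 1.01) and BOP2 (23.9-fold, log2 4.58 ± 0.56). The 6 largest falls were SFG1 (-3.09 ± 0.45), CYB5, cytochrome b5 (-3.05 ± 0.55), YGR035C (-2.94 ± 0.71), RRS1, of ribosome assembly (-2.75 ± 0.79), RFU1 (-2.74 ± 0.27) and HPT1, of purine salvage (-2.71 ± 0.51). MAG1, which removes methylated adenine, rose by 2.13 ± 0.42, adjusted p = 0.0074, and RAD54, of recombination repair, by 1.29 ± 0.31, adjusted p = 0.0146. On these arrays the median log2 excess of 3′ over 5′ signal in 8 yeast control genes was 0.77 at 30 min and 0.78 at 60 min, against 0.50 at 0 min of the same course and 0.51 and 0.53 on the early H2O2 arrays.

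Antioxidant genes rose in 22 of 31 cases and 1, SKN7, fell (median log2 1.22, camera adjusted p = 3.49e-08, adjusted p = 0.758 with an estimated correlation, 23 up and 1 down adjusted over the list alone). GTT2, a glutathione transferase, was at 4.11 ± 0.53, CTT1 at 1.97 ± 0.64 and YAP1 at 1.22 ± 0.22. Msn2/4 genes rose in 26 of 36 cases (median log2 1.61, camera adjusted p = 1.05e-09, adjusted p = 0.758 with an estimated correlation, 29 up and 0 down adjusted over the list alone). HXK1 was at 2.70 ± 0.68 and TSL1 at 3.50 ± 0.43. HSP12 was at 1.14 ± 0.85, adjusted p = 0.317. Autophagy genes rose in 16 of 21 cases (median log2 1.03, camera adjusted p = 4.37e-06, adjusted p = 0.758 with an estimated correlation). APE1 was at 3.85 ± 0.43 and ATG14 at 1.90 ± 0.29. Proteasome subunits rose in 15 of 33 cases (median log2 0.46, camera adjusted p = 1.45e-06, adjusted p = 0.758 with an estimated correlation, 26 up and 0 down adjusted over the list alone). RPT3 was at 0.77 ± 0.19, and RPN4, which is outside the list, at 1.09 ± 0.18. Hsf1 chaperones rose in 9 of 18 cases (median log2 0.39, camera adjusted p = 0.0145, adjusted p = 0.758 with an estimated correlation). BTN2 was at 1.93 ± 0.35 and HSP82 at 1.93 ± 0.32. Of the iron genes, 9 rose and 1, FTR1, fell (median log2 0.24, camera adjusted p = 0.0177, adjusted p = 0.758 with an estimated correlation, 12 up and 1 down adjusted over the list alone), led by ISU2 (2.39 ± 0.19) and MRS4 (2.39 ± 0.18). The ribonucleotide reductase regulon rose in 5 of 11 cases (median log2 0.67, camera adjusted p = 0.0441, adjusted p = 0.758 with an estimated correlation). PLM2 was at 2.16 ± 0.25, RNR3 at 1.91 ± 0.43, and RFX1, DUN1 and DIN7 passed as well. HUG1 was measured at 0.87 ± 0.55, adjusted p = 0.235. Of the DNA repair genes 13 rose and 3, RAD6, RAD55 and SRS2, fell without a call for the list (median log2 0.18, camera adjusted p = 0.125). RAD16 and RAD4, of nucleotide excision repair, rose by 1.44 ± 0.39 and 1.12 ± 0.25.

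Ribosome biogenesis genes fell in 39 of 89 cases (median log2 -1.19, camera adjusted p = 1.71e-14, adjusted p = 0.758 with an estimated correlation, 0 up and 60 down adjusted over the list alone). NOG1 was at -2.69 ± 0.66 and NOG2 at -2.59 ± 0.48. RNA polymerase I and III subunits fell in 10 of 21 (median log2 -1.14, camera adjusted p = 1.45e-06, adjusted p = 0.758 with an estimated correlation, 0 up and 12 down adjusted over the list alone). RPA12 was at -2.01 ± 0.41. Cytosolic ribosomal protein genes stood slightly below other genes, 5 lower and 1, RPL15B, higher of 128 (median log2 -0.17, camera adjusted p = 6.63e-05, adjusted p = 0.758 with an estimated correlation, 0 up and 1 down adjusted over the list alone). Histone genes fell in 8 of 9 cases (median log2 -0.71, camera adjusted p = 8.55e-05, adjusted p = 0.758 with an estimated correlation). HTB2 was at -1.82 ± 0.47 and HTA1 at -1.60 ± 0.24. Ergosterol synthesis genes fell in 8 of 24 cases (median log2 -0.52, camera adjusted p = 0.000214, adjusted p = 0.758 with an estimated correlation, 0 up and 9 down adjusted over the list alone). ERG1, squalene epoxidase, was at -1.79 ± 0.43 and ERG5 at -1.68 ± 0.39. Of the respiration genes 15 fell and 3 rose (median log2 -0.25, camera adjusted p = 0.00339, adjusted p = 0.758 with an estimated correlation), with the external NADH dehydrogenase NDE1 at -1.36 ± 0.25 and RIP1 at -1.35 ± 0.19 against CYC7 at 1.49 ± 0.42. The CLB2 cluster fell with 3 of 18 members passing, BUD3, CLB1 and CLB2 (median log2 -0.38, camera adjusted p = 0.0413, adjusted p = 0.758 with an estimated correlation, 0 up and 1 down adjusted over the list alone), CLB2 at -1.87 ± 0.35. The G1/S list was not called (median log2 -0.28, camera adjusted p = 0.0786, 5 up and 10 down adjusted over the list alone), with 5 genes up, RFA1, RFA2, POL30, PRI1 and RFC4 of replication, and 8 down, the latter including PCL1 (-1.45 ± 0.40) and CLN2 (-1.30 ± 0.34).

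In the early MMS window 1021 genes rose and 781 fell, 378 and 258 of them by 2-fold or more. With arrays centred on their medians the counts were 890 and 934, so that the excess of rises was not kept. The total of 1802 was 351 against the 0 min array of the MMS course and 50 with 30 min as the whole early window. It was 421 without the 60 min MMS array, and 351 or 459 without the 0 min array of the H2O2 or the MMS course.

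The late MMS window had the largest number of calls among the 9 contrasts, 4082 of 5449 genes. General stress, repair and proteasome genes rose as lists, and genes of ribosomal proteins, ribosome biogenesis, ergosterol synthesis and the CLB2 cluster fell. With an estimated correlation none of these list calls was kept. The 6 largest rises were DDI3 (196-fold, log2 7.61 ± 0.32, adjusted p = 1.53e-06), YNR064C, an epoxide hydrolase (114-fold, log2 6.83 ± 0.47), YNL194C (113-fold, log2 6.82 ± 0.72), TSA2 (112-fold, log2 6.81 ± 0.52), RTC3 (81.6-fold, log2 6.35 ± 0.58) and SOL4 (67.8-fold, log2 6.08 ± 0.63). The 6 largest falls were TOS6, a cell wall protein (33.3-fold, log2 -5.06 ± 0.50), CYB5 (33.0-fold, log2 -5.05 ± 0.50), PHO3, an acid phosphatase (30.5-fold, log2 -4.93 ± 0.52), URA7, CTP synthase (30.5-fold, log2 -4.93 ± 0.71), YGR035C (27.0-fold, log2 -4.76 ± 0.65) and DBP2, an RNA helicase (23.3-fold, log2 -4.54 ± 0.62). ACT1 was at 0.13 ± 0.08, adjusted p = 0.156. The median 3′ over 5′ excess of the 8 control genes was 0.86, 0.91 and 0.94 log2 at 100, 140 and 180 min, against 0.53, 0.63 and 0.68 on the late H2O2 arrays.

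Of the 36 Msn2/4 genes 35 rose (median log2 3.09, camera adjusted p = 8.75e-10, adjusted p = 0.586 with an estimated correlation). GPH1 was at 5.69 ± 0.71, PGM2 at 5.24 ± 0.67, DCS2 at 5.10 ± 0.56 and HSP12 at 4.50 ± 0.78. Antioxidant genes rose in 29 of 31 cases, and SKN7 again fell (median log2 1.60, camera adjusted p = 6.75e-06, adjusted p = 0.586 with an estimated correlation). OYE3 reached 6.02 ± 0.92, SRX1 5.97 ± 0.66, GTT2 4.79 ± 0.48, CTT1 2.78 ± 0.59 and GPX2 2.26 ± 0.89, whereas TSA1, TRX2 and TRR1 rose by 0.40 ± 0.13, 0.69 ± 0.14 and 0.92 ± 0.30. Autophagy genes rose in 19 of 21 cases and none fell (median log2 1.76, camera adjusted p = 4.74e-06, adjusted p = 0.586 with an estimated correlation). APE1 was at 4.93 ± 0.40, ATG14 at 3.23 ± 0.26 and ATG1 at 2.93 ± 0.32. All 33 proteasome subunit genes rose (median log2 0.88, camera adjusted p = 1.2e-06, adjusted p = 0.615 with an estimated correlation). RPT3 was at 1.34 ± 0.17, PRE8 at 1.24 ± 0.19 and RPN2 at 1.15 ± 0.15. RPN4 was at 1.25 ± 0.16. Hsf1 chaperones rose in 11 of 18 cases and HSP10 fell (median log2 0.83, camera adjusted p = 0.0384, adjusted p = 0.662 with an estimated correlation). HSP82 was at 2.60 ± 0.29 and HSF1 itself at 2.28 ± 0.22. Sulfur and methionine genes rose in 16 and fell in 4 of 25 cases, the falls being SAM1, SAM2, CYS4 and MET8 (median log2 1.06, camera adjusted p = 0.0363, adjusted p = 0.662 with an estimated correlation). MET2 was at 4.14 ± 0.62 and STR3 at 3.36 ± 0.46. Of the iron genes 15 rose and 4 fell, among the latter FET3 and FTR1 of high-affinity uptake (median log2 0.51, camera adjusted p = 0.0434, adjusted p = 0.586 with an estimated correlation).

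DNA repair genes rose in 27 and fell in 9 of 41 cases (median log2 0.60, camera adjusted p = 0.0141, adjusted p = 0.586 with an estimated correlation). RAD16 (3.28 ± 0.36, adjusted p = 5.85e-05) and RAD4 (2.36 ± 0.23, adjusted p = 4.53e-05) of nucleotide excision repair rose, as did MAG1 (2.94 ± 0.38, adjusted p = 0.000112), RAD54 (2.37 ± 0.28) and PHR1 (1.74 ± 0.24). The ribonucleotide reductase regulon split, 8 up and 3 down of 11, without a call for the list (median log2 1.11, camera adjusted p = 0.106). RNR3 (3.06 ± 0.39), HUG1 (2.91 ± 0.50), PLM2 (2.24 ± 0.23), RNR2 (0.84 ± 0.11) and RNR4 (0.68 ± 0.12) rose. RNR1, the main large subunit, fell by 1.63 ± 0.33, and TOS4 and SML1, the reductase inhibitor, fell too. Checkpoint genes rose in 8 and fell in 2 of 13 cases, also without a call (median log2 0.45, camera adjusted p = 0.349). RAD17 was at 1.23 ± 0.16, and the falls were RAD9 (-0.70 ± 0.12) and TEL1.

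All 89 ribosome biogenesis genes fell (median log2 -2.50, camera adjusted p = 6.83e-18, adjusted p = 0.586 with an estimated correlation). NSR1 was at -4.48 ± 0.71 and NOG1 at -4.44 ± 0.60. RNA polymerase I and III subunits fell in 20 of 21 cases (median log2 -1.96, camera adjusted p = 3.47e-06, adjusted p = 0.586 with an estimated correlation). RPA49 was at -3.77 ± 0.52. Cytosolic ribosomal protein genes fell in 126 of 128 cases and RPL15B alone rose (median log2 -1.30, camera adjusted p = 4.46e-24, adjusted p = 0.586 with an estimated correlation). RPL13A was at -2.98 ± 0.28 and RPS26B at -2.65 ± 0.26. Ergosterol synthesis fell in 21 of 24 cases (median log2 -1.38, camera adjusted p = 3.19e-06, adjusted p = 0.586 with an estimated correlation). ERG5 was at -2.98 ± 0.35 and HMG1, the reductase of the mevalonate pathway, at -2.86 ± 0.35. The CLB2 cluster fell in 14 of 18 (median log2 -1.62, camera adjusted p = 8.33e-05, adjusted p = 0.598 with an estimated correlation, 0 up and 15 down adjusted over the list alone). CLB2 was at -3.49 ± 0.32 and CHS2 at -2.60 ± 0.32. M/G1 and daughter-cell genes fell in 16 of 20 and MCM5 rose (median log2 -1.89, camera adjusted p = 0.000343, adjusted p = 0.586 with an estimated correlation). PIR1 was at -3.81 ± 0.44. Histone genes fell in 7 of 9 cases (median log2 -0.62, camera adjusted p = 0.00514, adjusted p = 0.586 with an estimated correlation), led by HTB2 (-4.19 ± 0.43). The mRNA decay machinery fell in 25 and rose in 10 of 46 cases (median log2 -0.42, camera adjusted p = 0.0363, adjusted p = 0.586 with an estimated correlation). The helicase DHH1 was at -1.48 ± 0.20 and EDC2 at 2.87 ± 0.25.

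The lists below a call held members that moved both ways. Of the G1/S genes 8 rose and 15 fell (median log2 -0.28, camera adjusted p = 0.106), with the cyclins PCL1 (-3.89 ± 0.36), CLN2 (-2.84 ± 0.31) and CLN1 (-2.37 ± 0.29) among the falls. Respiration genes rose in 18 and fell in 18 cases (median log2 0.01, camera adjusted p = 0.58, mean -0.03 with the test downward), with the cytochrome c isoforms apart, CYC7 at 2.81 ± 0.39 and CYC1 at -3.46 ± 0.41. The Gcn4 list (16 up, 12 down, median log2 0.01, camera adjusted p = 0.825, 15 up and 12 down adjusted over the list alone) had a mean of -0.05 and a test pointing downward. NADPH supply was 7 up and 6 down (median log2 0.01, camera adjusted p = 0.973). RKI1, ribose isomerase, was at -3.72 ± 0.51 and NQM1 at 3.11 ± 0.37. Mitochondrial ribosomal proteins (14 up, 16 down, median log2 -0.05, camera adjusted p = 0.58, 13 up and 14 down adjusted over the list alone), glycolysis (3 up, 6 down, median log2 -0.01, camera adjusted p = 0.58, 3 up and 5 down adjusted over the list alone) and pleiotropic drug resistance (7 up, 5 down, median log2 0.10, camera adjusted p = 0.908, 6 up and 4 down adjusted over the list alone) were near 0 at the median. The unfolded protein response (4 up, 4 down, median log2 0.11, camera adjusted p = 0.925) included ERO1 at 1.74 ± 0.17. Cell wall integrity (5 up, 9 down, median log2 -0.42, camera adjusted p = 0.184) included GAS1 at -2.50 ± 0.29, and the 5 rises were SLT2, MKK2, PIR3, GSC2 and CHS1. Of genes for other cell states, 14 of 23 sporulation genes rose and 3 fell, MEI4, IME1 and SPS4 (median log2 0.58, camera adjusted p = 0.208). Of the mating genes 8 of 22 fell and 5 rose, FUS3, GPA1, PRM5, STE6 and FUS2 (median log2 -0.16, camera adjusted p = 0.349).

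**Figure D2:**
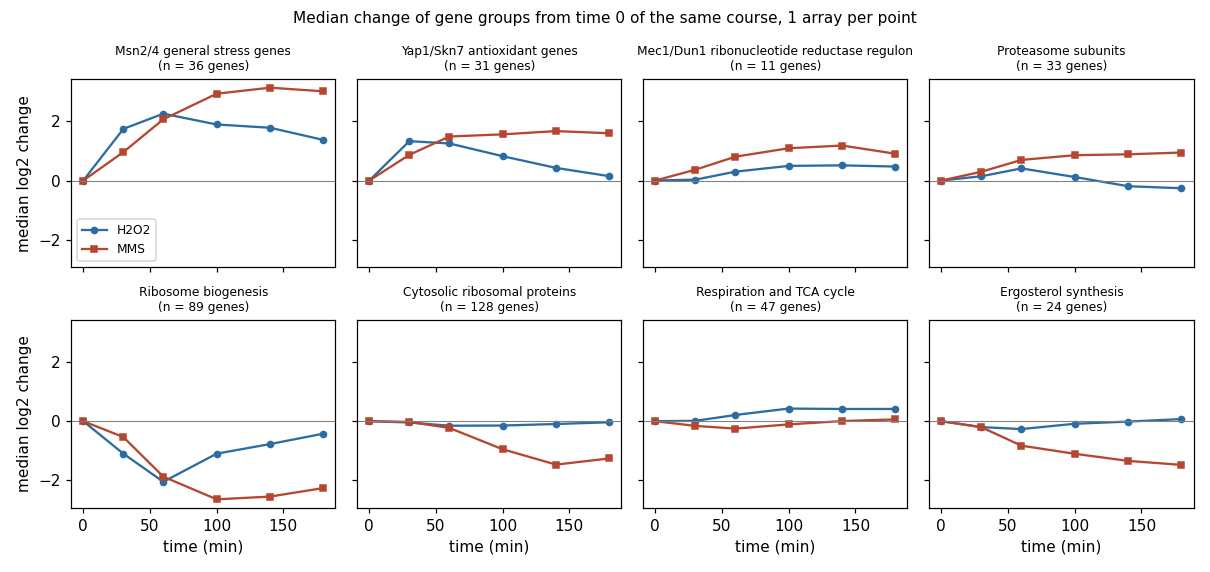
Median log2 change of the measured genes of 8 lists from the 0 min array of the same course, against time in min, for H2O2 (blue circles) and MMS (red squares), 1 array per point. The ribosome biogenesis median was -2.05 at 60 min of H2O2 and -0.42 at 180 min, against -1.88 and -2.26 after MMS, and the cytosolic ribosomal protein median was -0.04 at 180 min of H2O2 and -1.26 at 180 min of MMS. After MMS these medians were lowest before 180 min, ribosome biogenesis at 100 min (-2.64) and cytosolic ribosomal proteins at 140 min (-1.47). The ergosterol synthesis median was lowest at 180 min of MMS (-1.48).

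The late window called 2197 genes higher and 1885 lower than time 0, with 1016 and 885 of them 2-fold or more away. Tested late against early, 1479 genes were higher and 1169 lower, against 213 and 394 with an early window of 30 to 100 min. Msn2/4 genes rose further in 31 of 36 cases (median log2 1.60, camera adjusted p = 2.58e-08, adjusted p = 0.709 with an estimated correlation, 33 up and 0 down adjusted over the list alone). GPH1 was at 3.79 ± 0.71 and HSP26, a small heat shock protein, at 3.32 ± 0.55. Cytosolic ribosomal protein genes fell between the windows in 123 of 128 cases (median log2 -1.02, camera adjusted p = 4.48e-39, adjusted p = 0.709 with an estimated correlation). Ribosome biogenesis genes fell in 68 of 89 (median log2 -1.30, camera adjusted p = 2.38e-15, adjusted p = 0.709 with an estimated correlation, 0 up and 75 down adjusted over the list alone). TOS6 (-3.67 ± 0.50), PIR1 (-3.39 ± 0.44) and PTR2, a peptide transporter (-3.30 ± 0.44), fell, and HUG1 rose by 2.04 ± 0.50. MAG1 was at 0.81 ± 0.38, adjusted p = 0.104 and SRX1 at -0.65 ± 0.66, adjusted p = 0.436. The total of 2648 between the windows was 1602 with an early window of 30 min only, 607 with one of 30 to 100 min, and 620 without the 30 min MMS array.

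Across the stresses, early responses overlapped. Of the genes called early, 539 were higher after both stresses, against 150 expected from independent calls, 457 were lower after both, against 148 expected, and 16 went opposite ways. The contrasts share the time 0 arrays and each gene's spread, so their calls are not independent and the expected counts are only a rough mark. The early log2 changes correlated across genes at r = 0.846 (genes are not independent replicates), and r was 0.834 when each course was set against its own array at 0 min. Noise from the shared time 0 arrays alone gave r = 0.504 in 20 simulations, but with a covariance of 0.0314 against 0.515 measured. With 1 array at 0 min per course the time 0 group could not be divided further. Between single arrays r was 0.831 at 60 min of both courses and 0.533 at 180 min, and the 60 min H2O2 array reached 0.841 with the 100 min MMS array.

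The direct comparison of the stresses in the early window asked which early transcripts depended on the agent. DDI3 was far higher after MMS (56.9-fold, log2 5.83 ± 0.35, adjusted p = 4.59e-05), followed by YNR064C (19.8-fold, log2 4.30 ± 0.51), SSU1, the sulfite pump (8.25-fold, log2 3.04 ± 0.10, adjusted p = 4.66e-07), YSW1 (7.76-fold, log2 2.96 ± 0.25), FRE4 (3.41-fold, log2 1.77 ± 0.47) and STB6 (3.23-fold, log2 1.69 ± 0.14). Lower after MMS were YDL218W (-5.09 ± 1.01), DAK2, dihydroxyacetone kinase (-3.54 ± 0.33), PUT4, a proline permease (-3.51 ± 0.88), CTA1 (-2.93 ± 0.54), CTT1 (-2.59 ± 0.64) and AGX1 (-2.58 ± 0.35). Several shared responders did not differ by the test: SRX1 was at 0.02 ± 0.73, adjusted p = 0.988, MAG1 at 0.00 ± 0.42, adjusted p = 1, YAP1 at 0.06 ± 0.22, adjusted p = 0.902 and RNR3 at 0.34 ± 0.43, adjusted p = 0.654. These p-values do not show that the stresses acted alike on them. The median 3′ over 5′ excess of the control genes was 0.77 and 0.78 on the early MMS arrays against 0.51 and 0.53 on the early H2O2 arrays.

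Respiration and TCA cycle genes were lower after MMS than after H2O2 in 13 of 47 cases (median log2 -0.39, camera adjusted p = 2.7e-16, adjusted p = 0.3 with an estimated correlation, 0 up and 22 down adjusted over the list alone). CYC1 was at -2.06 ± 0.45 and CYT1 at -1.48 ± 0.12. NADPH supply genes were lower as a list (median log2 -0.37, camera adjusted p = 0.00222, adjusted p = 0.3 with an estimated correlation), with 0 of 15 members called by limma and 5 at an unadjusted p under 0.05. Msn2/4 genes were also lower as a list (median log2 -0.37, camera adjusted p = 0.00293, adjusted p = 0.768 with an estimated correlation, 0 up and 0 down adjusted over the list alone), with DDR2 alone called (-2.10 ± 0.51). G1/S and DNA replication genes were higher after MMS in 8 of 33 cases (median log2 0.33, camera adjusted p = 0.00232, adjusted p = 0.717 with an estimated correlation, 11 up and 0 down adjusted over the list alone). POL30, the sliding clamp, was at 1.08 ± 0.15. The Gcn4 amino acid genes were higher in 6 and lower in 2 of 48 cases (median log2 0.25, camera adjusted p = 0.0128, adjusted p = 0.768 with an estimated correlation, 12 up and 2 down adjusted over the list alone). TRP4 was at 1.06 ± 0.22 and LEU2 at -1.24 ± 0.18. The antioxidant list was lower with 2 of 31 members passing, CTA1 and CTT1, while ATR1 was higher (median log2 -0.11, camera adjusted p = 0.0283, adjusted p = 0.768 with an estimated correlation), a call that was lost when arrays were centred on their medians (camera adjusted p = 0.0582). In all, 313 genes were higher and 130 lower after MMS. After centring these counts were 167 and 195, so that the share of called genes that were higher moved from 70.7% to 46.1%. The total of 443 was 2 (DDI3 and SSU1) with each course set against its own 0 min array, 6 with 30 min only, 1021 with 30 to 100 min and 1000 with time point as a block. It was 148 and 205 without the 60 and the 140 min H2O2 array, 890, 184 and 243 without the 30, 60 and 140 min MMS array, and 244 without either array at 0 min.

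In the late window 3840 of 5449 genes differed between the stresses, and 1254 when each course was set against its own array at 0 min. Repair, proteasome and stress genes stood higher after MMS, and genes of translation, sterol synthesis and respiration stood lower. DDI3 (77.0-fold, log2 6.27 ± 0.28, adjusted p = 3.39e-06), YNR064C (55.1-fold, log2 5.78 ± 0.42), AAD6 (35.2-fold, log2 5.14 ± 0.37), SRX1 (29.3-fold, log2 4.87 ± 0.59), LSO1 (28.0-fold, log2 4.81 ± 0.68) and YKL070W (22.0-fold, log2 4.46 ± 0.48) were highest after MMS relative to H2O2. CYB5 (31.9-fold lower), TOS6 (23.2-fold, log2 -4.54 ± 0.44), PHO3 (20.6-fold, log2 -4.36 ± 0.47), URA7 (16.9-fold, log2 -4.07 ± 0.63), SRO9 (16.6-fold, log2 -4.05 ± 0.51) and CYC1 (16.3-fold, log2 -4.02 ± 0.36) were lowest. MAG1 (2.19 ± 0.34, adjusted p = 0.00033), RAD54 (2.06 ± 0.25, adjusted p = 8.38e-05), YAP1 (1.91 ± 0.18) and RPN4 (1.68 ± 0.14) were higher after MMS and RNR1 (-1.63 ± 0.30) lower. No difference was detected for HUG1 (-0.81 ± 0.45, adjusted p = 0.129), RNR3 (0.45 ± 0.35, adjusted p = 0.275), CTT1 (0.83 ± 0.53, adjusted p = 0.18), HSP12 (1.04 ± 0.70, adjusted p = 0.204) or ACT1 (0.04 ± 0.07, adjusted p = 0.659).

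On the late arrays the control genes' 3′ over 5′ medians were 0.86 to 0.94 after MMS and 0.53 to 0.68 after H2O2. DNA repair genes were higher after MMS in 30 and lower in 5 of 41 cases, the latter RAD6, REV7, SRS2, UNG1 and OGG1 (median log2 0.72, camera adjusted p = 0.00187, adjusted p = 0.561 with an estimated correlation). All 33 proteasome genes were higher (median log2 0.97, camera adjusted p = 2.63e-08, adjusted p = 0.561 with an estimated correlation), as were 20 of 21 autophagy genes, with ATG10 lower (median log2 1.19, camera adjusted p = 0.000142, adjusted p = 0.561 with an estimated correlation). So were 30 of 36 Msn2/4 genes (median log2 1.51, camera adjusted p = 0.000192, adjusted p = 0.561 with an estimated correlation, 31 up and 0 down adjusted over the list alone), 22 of 31 antioxidant genes, with SKN7 lower (median log2 0.83, camera adjusted p = 0.00187, adjusted p = 0.561 with an estimated correlation), and 12 of 18 Hsf1 chaperones, with SSC1 and HSP10 lower (median log2 0.73, camera adjusted p = 0.018, adjusted p = 0.561 with an estimated correlation). BTN2, a protein-sorting factor, was at 3.11 ± 0.28. Lower after MMS were 125 of 128 cytosolic ribosomal protein genes, with RPL15B higher (median log2 -1.22, camera adjusted p = 2.49e-28, adjusted p = 0.561 with an estimated correlation, 1 up and 126 down adjusted over the list alone), and 86 of 89 ribosome biogenesis genes (median log2 -1.75, camera adjusted p = 2.44e-15, adjusted p = 0.561 with an estimated correlation). Also lower were 22 of 24 ergosterol genes, with ERG8 higher (median log2 -1.36, camera adjusted p = 5.45e-08, adjusted p = 0.561 with an estimated correlation), and 26 of 47 respiration genes, with ATP7, MDH1, SDH2 and LSC1 higher (median log2 -0.41, camera adjusted p = 1.68e-05, adjusted p = 0.561 with an estimated correlation). ERG5 differed by -3.21 ± 0.31, RPL13A by -2.64 ± 0.25 and NSR1 by -3.75 ± 0.63. Cell wall integrity genes were lower in 11 of 20 cases and higher in 3, SLT2, CHS1 and MKK2 (median log2 -0.58, camera adjusted p = 0.0163, adjusted p = 0.561 with an estimated correlation, 3 up and 12 down adjusted over the list alone). GAS1 was at -2.19 ± 0.26. In total 2134 genes were higher and 1706 lower after MMS, 773 and 689 of them by 2-fold or more. After centring the counts were 1894 and 1947, so that the excess of higher genes was not kept.

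**Figure D3:**
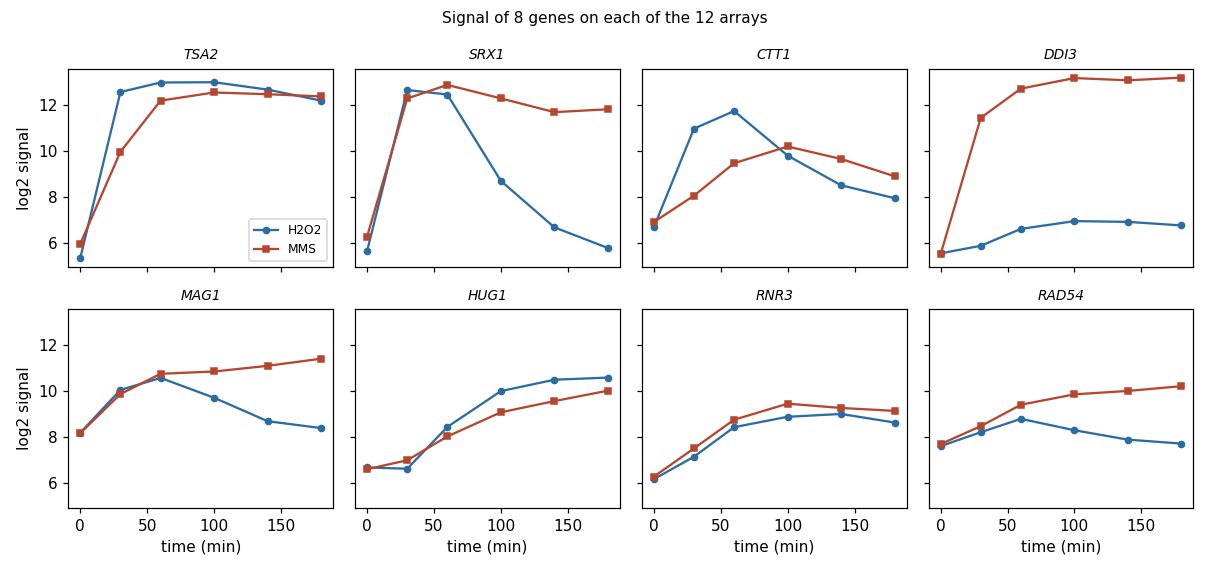
Log2 signal of 8 genes on each array against time in min, for H2O2 (blue circles) and MMS (red squares), 1 array per point. SRX1 stood at 5.63 at 0 min, 12.64 at 30 min and 5.77 at 180 min of H2O2, and at 11.80 at 180 min of MMS. At 180 min DDI3 stood at 13.18 after MMS and 6.75 after H2O2.

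Whether the stresses differed in how the response moved from the early to the late window was tested as a difference of differences. For 2435 genes the move differed, 1249 of them with a more upward move after MMS and 1186 with a more downward one. SRX1 (4.85 ± 0.94, adjusted p = 0.00867), CTA1 (4.32 ± 0.70), OYE3 (4.54 ± 1.31) and CTT1 (3.42 ± 0.83, adjusted p = 0.0129) receded between the windows after H2O2 and less or not at all after MMS. MAG1 (2.19 ± 0.54, adjusted p = 0.0136) and RAD54 (1.62 ± 0.40, adjusted p = 0.0132) differed in the same direction, and so did STR3 (3.96 ± 0.66) and SOL4 (3.41 ± 0.89). RNR1 (-2.33 ± 0.47, adjusted p = 0.00892), PCL1 (-3.83 ± 0.51) and RPA135 (-3.14 ± 0.62) moved the other way. For HUG1 (-0.79 ± 0.70, adjusted p = 0.381) and RNR3 (0.10 ± 0.55, adjusted p = 0.893) no difference was detected. Ribosome biogenesis had the largest shift among the lists, 84 of 89 genes (median log2 -2.17, camera adjusted p = 5.07e-20, adjusted p = 0.513 with an estimated correlation, 0 up and 88 down adjusted over the list alone). Of the cytosolic ribosomal protein genes 116 of 128 moved the same way (median log2 -1.10, camera adjusted p = 6.04e-29, adjusted p = 0.513 with an estimated correlation, 1 up and 121 down adjusted over the list alone). All 33 proteasome genes moved upward after MMS relative to H2O2 (median log2 0.79, camera adjusted p = 1.47e-08, adjusted p = 0.513 with an estimated correlation). The total of 2435 became 17 with windows of 30 min and of 60 to 180 min. With windows of 30 to 100 min and of 140 and 180 min 0 genes were called by limma, and 1862 genes had an unadjusted p under 0.05. The total was 1343 without the 60 min H2O2 array and 1072 without the 30 min MMS array.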

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

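The tests against the added poly-A transcripts, of labelling and of cellular RNA were chosen after the results were seen, whereas those on signal-matched genes, on length-matched genes and on other splits of the arrays were written before. The change from the early to the late window differed between the stresses for 2435 genes by the test of that difference. That count depended on the choice of windows. With an early window of 30 to 100 min, 0 genes were called by limma and 1862 had an unadjusted p under 0.05. The count was also lower with an early window of 30 min only, which leaves 1 array in each early window. With the main windows, the change differed among always-named genes for SRX1 (4.85), CTT1 (3.42), MAG1 (2.19), YAP1 (1.86), RAD54 (1.62), PHR1 (1.48) and RPN4 (1.19), all higher after MMS, in log2. RNR1 (-2.33) differed as well and was lower after MMS. Among the lists, the median log2 difference was 1.69 for Msn2/4 genes, 1.25 for autophagy, 1.02 for sulfur and methionine, 1.01 for antioxidant genes, 0.79 for the proteasome, 0.56 for DNA repair and 0.56 for Hsf1 chaperones. It was -2.17 for ribosome biogenesis, -1.56 for RNA polymerases I and III, -1.45 for M/G1 genes, -1.29 for the CLB2 cluster, -1.20 for ergosterol synthesis, -1.10 for cytosolic ribosomal proteins, -0.64 for G1/S genes and -0.22 for Gcn4 genes. Each of these list calls was lost with an estimated correlation, with adjusted p-values from 0.513 to 0.655. Of the 218 probe sets with no listed gene, which stood outside the comparisons, 168 differed from time 0 in the late MMS window, 112 of them higher and 56 lower. Of the genes tested, 4082 of 5449 (74.9%) were called in that contrast, so a large share was not particular to these probe sets. For the late difference between the stresses, the real grouping of the 6 arrays called 3840 genes and was 1 of 10 splits. The other splits called at most 0 genes by limma, with 3 to 138 genes at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05. Each of them also mixes both stresses in both groups, so that the stress difference enters the spread and few calls can follow. Their count is therefore no support for the real grouping.

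Cytosolic ribosomal protein genes had a median log2 change of -1.30 in the late MMS window. Array scaling of bright genes as the whole cause is argued against by 128 other genes matched on signal at time 0, whose median was -0.28 (95% bootstrap interval -0.533 to -0.132). The match was incomplete, with a median signal at time 0 of 12.53 for these genes and 12.71 for the ribosomal protein genes. For 128 other genes matched on annotated gene length (median 771 for both sets), the median was 0.0883 (interval -0.106 to 0.313). This length is the span from gene start to gene end with any introns. RNA quality acting through that span is argued against. The length of the mRNA was not matched, so an effect through it stays open. A rise in total mRNA against the added transcripts would lower their signal, and the lowest of their 4 changes was 0.10 log2. These changes are means over the late arrays, which differed. The added control DapX-M stood at 7.85, 8.37 and 8.45 log2 at 100, 140 and 180 min, against 8.35 and 8.10 at 0 min. LysX-5 stood at 4.44, 4.97 and 5.18, against 4.42 and 4.08. The means therefore do not settle the 100 min array. A change in the levels of ribosomal protein transcripts under MMS may remain as a hypothesis, and neither synthesis nor decay was measured.

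The 3′ over 5′ signal of 8 yeast control genes, probe sets outside the comparisons, reached a median of 0.94 log2 on an MMS array, against 0.50 and 0.69 on the arrays at 0 min. A weaker labelling reaction is argued against by the added transcripts, whose 3′ over 5′ signal changed by a median of -0.33 on the MMS arrays (range -0.46 to -0.10). For the cellular RNA itself the median change was 0.22 and 6 of 8 control genes rose, and 6 of 8 also rose on the H2O2 arrays with a median of 0.02. These changes, like those of the added transcripts, are against the mean of both 0 min arrays, which were unlike. Within the MMS course the median was 0.50 at 0 min and 0.77 to 0.94 after. Within the H2O2 course it was 0.69 at 0 min and 0.51 to 0.68 after, so the equal counts do not show an equal rise. Shortened RNA and adducts that block reverse transcription could both raise the ratio, and with 1 array per time point these values leave both open.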

How the results depend on the processing

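All alternatives were planned, and none was chosen after the results were seen. No paired analysis was possible because the labels give no culture or batch that joins an H2O2 array to an MMS array, and the replicate numbers only count time points. Time point as a block was run instead. No called gene named here changed the sign of its log2 change, and no list was called in opposite directions. The balance of higher to lower genes did turn. With median centring it was 911 to 884 for early H2O2, 890 to 934 for early MMS, and 167 to 195 and 1894 to 1947 for the stresses early and late. For early H2O2 it was 324 to 276 with its own 0 min array and 150 to 111 with a 30 min window, and for MMS late against early 213 to 394 with a 30 to 100 min window. For the difference of differences it was 6 to 11 with a 30 min window, 1014 to 1040 without the dimmest genes and 1022 to 1037 without MMS 180 min. For H2O2 late against early it was 490 to 475 without MMS 30 or 60 min. Median centring, quantile normalization, a mean-variance trend, the mean of all probe sets and all probe sets except controls left the 9 counts of called genes within 1.5 times. Against the 0 min array of the same course the counts were 600 of 1834 for early H2O2, 6 of 839 for late H2O2, 351 of 1802 for early MMS, 266 of 494 for H2O2 late against early, 2 of 443 for the stresses early and 1254 of 3840 late, and this fit has 6 residual degrees of freedom and 1 array at 0 min per course. With an early window of 30 min only, and so a late one of 60 to 180 min, they were 261 for early H2O2, 50 for early MMS, 87 for H2O2 late against early, 1602 of 2648 for MMS late against early, 6 for the stresses early and 17 of 2435 for the difference of differences. With an early window of 30 to 100 min, and so a late one of 140 and 180 min, they were 1122, 22 for late H2O2, 16, 607, 1021 for the stresses early and 0 by limma for the difference of differences, where 1862 genes had an unadjusted p under 0.05. The cause was not tested for these windows. Leaving out the dimmest 25% of genes gave 302 for H2O2 late against early, over fewer genes. Time point as a block gave 1000 for the stresses early, and the cause was not tested. Leaving out each array in turn gave 585 to 2235 for early H2O2, 6 to 1271 for late H2O2, 351 to 2664 for early MMS, 3548 to 4126 for late MMS, 85 to 965 and 620 to 3054 for late against early of H2O2 and MMS, 148 to 890 and 3471 to 3902 for the stresses early and late, and 1072 to 3009 for the difference of differences. Early H2O2 was 817 without its 60 min array and 585 or 600 without the 0 min array of the H2O2 or MMS course. Late H2O2 was 232 and 138 without its 100 and 140 min array, 516 without MMS 140 min, 9 and 6 without either 0 min array, and 1271 without MMS 30 or 60 min. Early MMS was 421 without its 60 min array and 351 or 459 without a 0 min array. H2O2 late against early was 85, 129 and 147 without its 30, 140 and 180 min array, 269 without MMS 140 min, 266 without either 0 min array and 965 without MMS 30 or 60 min. MMS late against early was 620 without MMS 30 min. The stresses early gave 148 and 205 without H2O2 60 and 140 min, 890, 184 and 243 without MMS 30, 60 and 140 min, and 244 without either 0 min array. The difference of differences was 1343 without H2O2 60 min and 1072 without MMS 30 min. An early window left with 1 array was assumed to vary like the other groups. For a window against time 0, the fit with the own 0 min array is the same as leaving out the 0 min array of the other course. For late against early no 0 min array enters the contrast. There the own-array fit equals leaving out either 0 min array and only drops that pair from the spread. These are not separate checks. All 139 list calls were lost with the estimated correlation. With fry, which asks the different question of change in the list itself, 48 were lost and 17 gained. Own 0 min arrays lost 8 list calls and gained 5, median centring lost 3 and gained 2, and leaving out the dimmest 25% of genes lost 12 and gained 3. Of 1223 named-gene results, 467 lost their call with the 30 min window, 344 with the 30 to 100 min window and 310 with the own 0 min arrays. Of the counts per time point, all 10 moved with a fold threshold of 1.5, all 10 with 3, and 3 without the dimmest genes, H2O2 140 and 180 min and MMS 30 min, all to lower counts over fewer genes. Signal over background was not used here, and dim genes carry the least certain changes.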

Other observations

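Families of genes that share the letters of their name were screened after the data were examined, and the test on ADA2 was also chosen after the result was seen. The screen took 110 families of 8 or more members in 6 contrasts with camera, and every call named here was lost with an estimated correlation (adjusted p = 0.835). After early H2O2, nucleoporin (NUP) genes were lower in 16 of 20 cases (median log2 -0.42, adjusted p = 6.39e-05) and tRNA methylation (TRM) genes in 14 of 15 (median log2 -1.15, adjusted p = 2.44e-05). SDH genes, which include succinate dehydrogenase and 4 members of the respiration list, were higher in 8 of 8 cases in the late H2O2 window (median log2 1.02, adjusted p = 5.36e-05).

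In the late MMS window, vacuolar protein sorting (VPS) genes were higher in 33 of 40 cases and lower in 1 (median log2 0.83, adjusted p = 6.3e-05). TRM genes were lower in 13 of 15 cases (median log2 -1.42, adjusted p = 0.00107). The TIM and TOM families, which mostly hold mitochondrial protein import genes, were lower. TIM genes were lower in 10 of 14 cases (median log2 -0.49, adjusted p = 0.0307) and TOM genes in 7 of 9 (median log2 -0.75, adjusted p = 0.0451). Genes named TIF, mostly of translation initiation, were lower in 8 of 9 cases (median log2 -0.62, adjusted p = 0.0088) and GPI anchor (GPI) genes in 10 of 13 (median log2 -0.50, adjusted p = 0.00711). TIF6 is also a member of the ribosome biogenesis list. Set against H2O2 in the late window, genes for TATA-binding-protein-associated factors (TAF) were higher in 12 of 14 cases (median log2 0.63, adjusted p = 0.0166) and COX genes of cytochrome oxidase and its assembly lower in 12 of 19 (median log2 -0.65, adjusted p = 0.018). Several COX genes are also members of the respiration list, which was lower in the same contrast, so this is not a separate observation.

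ADA2, a transcriptional adaptor gene, was 5.55 log2 at 0 min of the H2O2 course and 7.55 at 0 min of the MMS course. Its lowest signal on an MMS-course array was 6.80 and its highest on an H2O2-course array 5.55, a gap of 1.25 log2. On all arrays 1 of 5449 genes (0.0184%) stood apart between the courses by 0.5 log2 or more. That count cannot exclude a general difference between the courses' arrays, because stress responses and normalization could hide one. At 0 min 98.8% of genes lay within 0.5 log2 of each other and 37 were 1.5-fold or more apart. A gap as large as that of ADA2 was therefore not general at 0 min. YEL076C-A, YFL065C, YEL076C and TOP3 were also 2-fold or more higher at 0 min of the MMS course. YLR462W (2.99 and 4.04) and YDR034C-A (3.56 and 2.05) differed as much, but near the 2.22 to 3.49 of the Tag control probe sets. The labels name no strain, and a difference of strain or culture between the courses was not tested. It would enter the direct comparisons of the stresses.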
